A study of Mus musculus with 35 samples.

How the data were processed

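Each array hybridised digoxigenin-labelled cDNA made from total RNA of 10 µm frozen sections, following the array maker's standard protocol. The imaging software, the background correction and the filter that chose the probes of the authors' normalized table are not given in the sources used here.

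Values came from a pair of tables. The series table held 33012 probes for all 35 arrays and was not normalized between arrays: array medians ran from 557.79 to 1292.16 intensity units in set 1 and from 655.665 to 1513.66 in set 2. A separate table held 12688 probes for the 11 arrays of set 2 and was quantile normalized by the authors, according to the text deposited with it. All 11 of its columns had identical sorted values with a median of 18933. Each rank carried the highest of the 11 unnormalized arrays at that rank, in 100% of ranks within a relative tolerance of 1e-06. The rank order of each array was that of its own column in the series table (lowest Spearman rho 1). Levels in the authors' table are therefore higher than array intensities, and no level was compared between the sets without saying so. All columns could be mapped to a sample (0 not mapped).

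Set 2 was tested on the authors' table. The plan had been to test set 1 on the deposited values as they stood, on the assumption that they were normalized. As they were not, set 1 was quantile normalized here with limma, a choice made after the files were seen, and the unnormalized values became an alternative. In set 1, 16 probes lacked a value on at least 1 array and were left out, which left 32996. After scaling, intensities below the 1st percentile of the set (168.105 in set 1, 878.91 in set 2) were raised to it, and log2 values were taken. A change that involves an array at this floor is a lower bound. No probe was filtered out for low signal.

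Linear models with an intensity trend in the variance prior were fitted per probe with limma (lmFit and eBayes), separately in each set and with all groups of the set in the model. Tests were two-sided, p values were adjusted over all probes of the set by the Benjamini-Hochberg method, and an adjusted p under 0.05 passed. The trend with weight was fitted on log10 grams, so its values are log2 changes per 10-fold weight. limma's moderated F test asked for any difference among the 4 tumor sizes or the 4 stages. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

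Gene symbols came from the authors' table and were updated through synonyms of the RefSeq annotation of GRCm38.p6, which was used for names alone. Of the 12688 probes, 8354 carried a single symbol, 150 several and 4184 none. Of the symbols, 5010 were current, 3087 were updated and 257 were kept as deposited. These probes named 7804 genes. The other 20324 probes of the series table had no name pairing and entered the counts of set 1 without a name. Of 488 genes with several probes, the probe with the highest mean in the set stood for the gene. Among such genes a second probe was called the other way for Magi1 in very large against small tumors, for Gnai2 in the weight trend, for 18 of the 242 called in set 2 tumors against day 0 ganglia and for 16 of the 243 called against day 14 ganglia.

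The groups, comparisons, gene lists, key genes, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest named genes past the threshold with non-overlapping groups for the main pairwise comparisons, and 5 and 5 for the trend and the other comparisons. It also took up to 4 members per list by smallest p and the key genes that had a named probe, among them Mycn, Cenpe, Th, Dbh, Vegfa and Cdkn1a. Mki67 had none. Some genes chosen by this rule are not reported here. The key genes were tested with all other probes.

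Of 26 lists, those with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 between genes, on 1 probe per gene, with adjustment over the lists. The lists tested were kinetochore and mitotic kinesins, mitotic entry and exit, DNA replication and E2F targets, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, polycomb, chromatin and progenitor genes, noradrenergic and chromaffin genes, neuronal maturation and synapse, Schwann cells and satellite glia, endothelial cells, hypoxia and glycolysis, macrophages and other myeloid cells, fibroblasts and extracellular matrix, adrenal cortex, skeletal muscle, adipocytes, interferon response, MHC class I presentation, p53 targets and apoptosis, immediate-early genes, heat shock and chaperones, imprinted fetal growth genes, and cholesterol synthesis. Lists with fewer than 5 measured genes were not tested: T and B lymphocytes (3 measured), kidney epithelium (1) and erythroid cells (2, Hba-a1 and Alas2). Cryab stood in both the Schwann cell and the heat shock list. Every list was also tested with the correlation estimated from the residuals.

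The procedure was tried on simulated arrays with each probe's noise in these sets, in which 200 probes were changed. Noise was drawn independently for each probe, so the list results do not cover genes that vary together. Of 2-fold changes it found 35% for very large against small tumors, 67% for the trend, and 34%, 31% and 22% for set 2 day 7, day 14 and tumors against day 0. Of 4-fold changes it found 83%, 97%, 82%, 80% and 71%. False calls numbered 6, 11, 6, 2 and 1. The kinetochore list, shifted by 1 log2 unit (per 10-fold weight for the trend), was found in 20 of 20 draws in each case. Smaller list shifts, such as those of the MYC target and cell cycle lists in set 1, were not tried. Over 20 draws with no list shifted, false list calls numbered 0, 0, 1, 2 and 1.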

Results

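Gene expression was measured with single-colour oligonucleotide arrays in TH-MYCN mice, a model in which a human MYCN transgene driven by the tyrosine hydroxylase promoter gives rise to neuroblastoma. The mice were homozygous for the transgene and were followed by ultrasound after weaning. Set 1 held 24 tumors, 6 in each of 4 size classes. Small tumors weighed 0.05 to 0.1 g (0.08 ± 0.02 g, mean ± SD, n = 6), medium ones 0.24 to 0.46 g (0.35 ± 0.09 g), large ones 0.76 to 1.3 g (0.94 ± 0.22 g) and very large ones 1.6 to 3 g (2.04 ± 0.59 g). Set 2 held 9 hyperplastic sympathetic ganglia, the lesions from which these tumors arise, from postnatal day 0 (n = 5), day 7 (n = 2) and day 14 (n = 2), and a further array of 2 of the small tumors (small replicates 3 and 6). The series names CENPE, a kinesin that moves chromosomes at the kinetochore, as a neuroblastoma target. The number of arrays, above all the groups of 2 in set 2, limits the precision of every value.

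Array medians before scaling ran from 557.79 to 1292.16 intensity units in set 1 and from 655.665 to 1513.66 in set 2. The mean Pearson's r of an array with the others of its group, across probes, lay between 0.932 and 0.963 in set 1, and at 0.950 to 0.968 for day 0. By their specimen names the day 0 ganglia fall into 2 series, replicates 1 and 2 and replicates 3 to 5, and every comparison with day 0 rests on both. Single pairs had r = 0.965 to 0.985 within the second series, 0.955 within the first and 0.941 to 0.954 between them, while day 0 replicates 1 and 2 had r = 0.955 to 0.959 with the day 7 arrays. Further, r was 0.977 for the pair of day 7, 0.984 for that of day 14 and 0.989 for the tumors of set 2. Probes are not independent replicates. The first 3 principal components held 12.1%, 7.72% and 6.56% of the variance in set 1, and 47.0%, 16.4% and 10.6% in set 2. The titles name separate specimens, and nothing else in the labels pairs animals.

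Life span, the age at which a mouse was killed, rose with tumor weight. Its mean was 31.3 days for small, 37.2 for medium, 39.3 for large and 40.2 for very large tumors. Over the 24 mice the 2-sided permutation tests gave r = 0.479 (p = 0.0152, adjusted over 2 relations 0.0152) and rho = 0.535 (p = 0.00712, adjusted 0.00712), with r = 0.482 without the 2 tumors of most extreme weight. On log10 weight r was 0.598 (permutation p = 0.0024, adjusted 0.0048), and 0.483 without the 2 tumors of most extreme log10 weight. These were the tumors of 0.05 g, whereas those of 2.55 and 3 g were left out on the plain scale. The relation was not seen within size classes: r was −0.045 in small (exact permutation p = 0.9), −0.890 in medium (exact p = 0.0333), −0.476 in large (exact p = 0.333) and 0.231 in very large tumors (exact p = 0.6). Age and size class are thus partly confounded.

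The comparison of very large with small tumors asks what changes over the full range of growth. Several of the named genes that fell most were genes of brown fat and muscle. Thrsp, a regulator of lipid synthesis, fell by 4.56 log2 units (SE 0.59, adjusted p = 9.0e-05). Cox8b and Cox7a1, cytochrome oxidase subunits of muscle and brown fat, fell (−4.29 and −3.99), as did Ucp1, the uncoupling protein of brown fat (−3.73), Pdk4 (−3.91), Agpat2 (−3.73), Fmo1 (−4.01) and Mrap (−3.47). The BMP antagonist Sostdc1 also fell (−4.44). Hbb-y, an embryonic beta-like globin, rose by 3.05 (SE 0.53, adjusted p = 0.00112), followed by Noc2l (1.64), BC024561 (1.62), Ppnr (1.60), Aatf (1.57), Nr2f1 (1.47), Dpp6 (1.34), the neurotensin receptor Ntsr2 (1.33, SE 0.19), Ccn2 (1.29) and Hnrnpdl (1.25). For each of these genes all 6 very large tumors lay on the same side of all 6 small ones, because the rule for naming genes required it.

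Mycn (probe 355859) fell from a log2 level of 11.19 ± 0.66 (SD, n = 6) in small to 8.67 ± 0.52 (n = 6) in very large tumors, a change of −2.52 (SE 0.54, adjusted p = 0.0064). Whether this probe also reads the human transgene is not given in the sources used here. Dbh, the enzyme that makes noradrenaline, fell from 13.93 ± 0.48 to 12.75 ± 0.36 (−1.19, SE 0.25, adjusted p = 0.0059). Cenpe (probe 675134) rose from 13.81 ± 0.18 to 14.34 ± 0.19 (0.53, SE 0.15, adjusted p = 0.0348), with all 6 very large tumors above all 6 small ones. Th (0.11, adjusted p = 0.887), Vegfa (0.64, 0.13) and Cdkn1a (−1.66, 0.073) did not pass, although Vegfa did without small replicate 1 (0.0273) and Cdkn1a without small replicate 1 (0.0461) or very large replicate 1 (0.0468). With life span as a covariate none of the first 3 passed: Mycn −1.67 (adjusted p = 0.277), Dbh −0.65 (0.339), Cenpe 0.56 (0.2). With the muscle and adipocyte levels as covariates they were −2.29 (0.275), −1.49 (0.0865) and 0.37 (0.612). The Cenpe call was also lost with arrays centred on their medians (0.29, adjusted p = 0.355), without normalization (0.02, 0.979, or 0.29 relative to all probes) and without the intensity trend (0.0759). It was lost as well, at an adjusted p of 0.0600 to 0.0876, without small replicate 3, 4 or 6 or very large replicate 2, 3, 4 or 5. Over all alternatives other than single arrays its adjusted p ran from 0.0189 to 0.979.

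**Figure D1:**
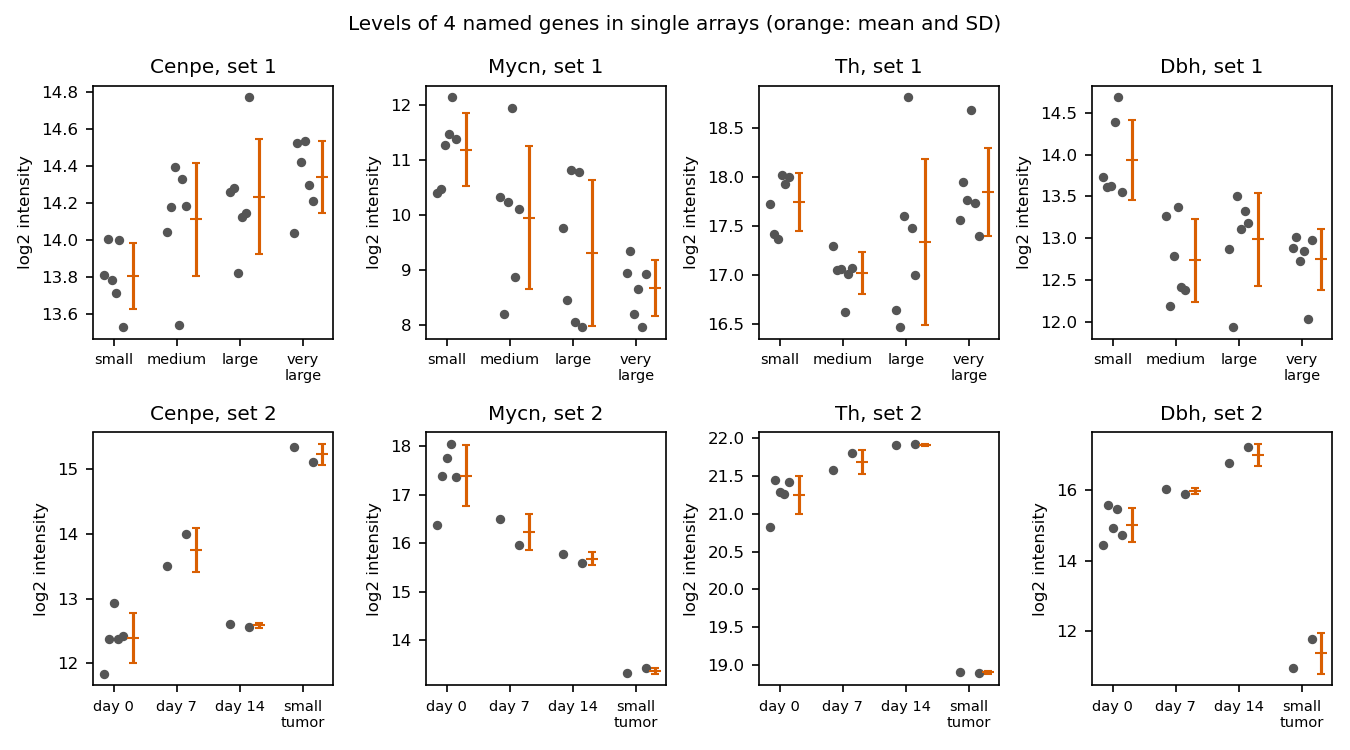
Log2 intensity of Cenpe, Mycn, Th and Dbh on each array (points) with the group mean and SD (orange), for the 4 size classes of set 1 (top, n = 6 each) and for ganglia of day 0 (n = 5), day 7, day 14 and small tumors (n = 2 each) of set 2 (bottom). Cenpe stood at 13.81 in small and 14.34 in very large tumors of set 1, and at 12.39 in day 0 ganglia and 15.23 in tumors of set 2; levels cannot be compared between the sets, which were scaled separately.

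Skeletal muscle and adipocyte genes were lower in larger tumors. Of 12 muscle genes 6 fell (11 adjusted over the list alone), among them Tnnc2 (−4.43), Ckm (−4.33) and Casq1 (−3.67), with a list median of −3.87 (camera adjusted p = 8.9e-06, and adjusted p = 0.406 with an estimated correlation). Of 9 adipocyte genes 4 fell (8 adjusted over the list alone), with Pnpla2 at −1.68 and Dgat2 at −1.37, and a list median of −1.62 (adjusted p = 8.9e-06, and adjusted p = 0.222 with an estimated correlation). Both lists passed in medium and large tumors as well, and the lists described next moved beside them.

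MYC targets and ribosome biogenesis genes were higher: 4 of 15 rose and 0 fell (8 and 0 adjusted over the list alone), among them Srm by 0.65, Nolc1 by 0.53, Ddx21 by 0.47 and Ipo4 by 0.37. The list median was 0.32 (adjusted p = 7.3e-04, and adjusted p = 0.222 with an estimated correlation), 0.13 with centred arrays, and −0.14 without normalization, where the median of all probes lay at −0.26. Of 23 kinetochore genes 2 rose (2 adjusted over the list alone), Cenpe and Spc24 (0.68, SE 0.17), while none of 19 mitotic and none of 19 DNA replication genes passed in limma. The medians of these 3 lists were 0.23, 0.14 and 0.16 (adjusted p = 0.0355, 0.0434 and 0.0274), and each had an adjusted p of 0.505 with an estimated correlation. With centred arrays their medians were 0.01, −0.03 and −0.02 and none passed, and without normalization they were −0.26, −0.30 and −0.29, beside the −0.26 of all probes, and none passed. None of the 3 passed with muscle and adipocyte levels as covariates (adjusted p = 0.252, 0.147 and 0.124), nor did the kinetochore and replication lists without small replicate 1 (0.0849 and 0.0523), small replicate 6 (0.0946 and 0.0539) or very large replicate 2 (0.0544 for both). The kinetochore list was also lost without very large replicate 3 (0.0562). The mitotic list was lost in 7 of 12 fits with 1 array left out, without small replicate 1, 3 or 6 or very large replicate 1, 2, 3 or 6 (0.0511 to 0.0946), and its median was 0.08 without small replicate 6. The calls of the cell cycle lists in set 1 therefore depend on the scaling and on single arrays.

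Neuronal and glial genes were lower. Of 23 neuronal genes 4 fell and 1 rose (9 and 2 adjusted over the list alone), with Prph, the intermediate filament of peripheral neurons, at −2.86 (SE 0.44), Gap43 at −0.81, Uchl1 at −0.66 and Syt1 at 0.51. The list median was −0.44 (adjusted p = 0.0036, and adjusted p = 0.222 with an estimated correlation). Of 10 Schwann cell genes 4 fell (6 adjusted over the list alone), with Fabp7 at −3.91, Gpr37l1 at −2.71 (1 of 6 very large tumors at the floor) and Cryab at −1.48. The list median was −1.37 (adjusted p = 0.00265; adjusted p = 0.0814 with an estimated correlation). Interferon response genes had a median of −0.66, with 1 of 9 past (2 adjusted over the list alone), the chemokine Cxcl10 at −3.11 (list adjusted p = 0.0434, and adjusted p = 0.505 with an estimated correlation; 0.404 with the tissue covariates). Without small replicate 1 the interferon median was −0.28 (0.196), and the call was lost in 8 of 12 fits with 1 array left out, also without small replicate 3 or 4 or very large replicate 1, 2, 3, 5 or 6 (0.0500 to 0.0780). Cholesterol synthesis genes had a median of −0.34, with 1 of 17 past (5 adjusted over the list alone), Mvk at −1.45 (list adjusted p = 0.0355, and adjusted p = 0.505 with an estimated correlation; 0.54 with life span as a covariate and 0.0622 without small replicate 5). The cholesterol median was −0.22 without very large replicate 3.

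The other 13 lists did not pass. Noradrenergic genes went both ways, 2 of 20 up and 5 down (3 and 7 adjusted over the list alone), with Chgb at 1.12, Phox2a at −1.08 and Slc18a2 at −1.08 (list median −0.20, adjusted p = 0.257). Of 19 fibroblast genes 5 fell and 1 rose, among them Lum (−3.01), Ogn (−1.87), Mmp2 (−1.44) and Fbln2 (0.79), at a list adjusted p of 0.144 (0.0313 without very large replicate 2). MHC class I genes had a median of −0.43 (0.0682), with Tap1 at −1.71 and Calr at −0.57, and endothelial genes a median of 0.32 (0.0686, or 3.2e-05 with the tissue covariates). The MHC list passed without small replicate 4 or 5 or very large replicate 4 (0.0283 to 0.0484), and the endothelial list without small replicate 1, 4 or 6 or very large replicate 1, 4 or 6 (0.0153 to 0.0484). Adjusted p values were 0.0781 for ribosomal proteins, 0.175 for p53 targets (with Trp53inp1 at −1.26, Phlda3 at −1.04 and Ei24 at −0.41), 0.346 for immediate-early genes, 0.499 for myeloid cells, 0.58 for heat shock genes, 0.886 for imprinted genes (Sgce 0.74, Cdkn1c −0.71) and 0.96 for hypoxia genes (Egln3 −2.78). For polycomb genes the median of 0.18 and the mean of −0.02 differed in sign (0.28), and for the adrenal cortex the median was 0.05, the mean −0.72 and the test negative (0.321).

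In all, limma called 1549 probes in this comparison, 742 higher and 807 lower, of which 235 and 502 changed at least 2-fold. They included 806 named genes, 314 higher and 492 lower. With centred arrays the split was 222 higher and 915 lower, and without normalization, which moved the median of all probes to −0.26, it was 25 and 527. The count was 827 without small replicate 4 and 1002 without very large replicate 5, 272 with life span as a covariate and 12 with muscle and adipocyte levels as covariates.

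Medium tumors, the first step beyond the small class, already showed the loss of muscle and fat genes. Thrsp (−4.22, SE 0.59), Ppara (−3.57, with 1 of 6 medium tumors at the floor), Fmo1 (−3.54), Cox7a1 (−3.36) and Mrap (−3.24) fell, while Fkbp11 (0.98, SE 0.20), Bhlha15 (0.54), Iars (0.55), Nxt1 (0.50) and BC016608 (1.49) rose. Of 12 muscle genes 6 fell (11 adjusted over the list alone), such as Myl1 (−6.81) and Casq1 (−4.67), with a median of −4.74 (adjusted p = 4.0e-11, and adjusted p = 0.119 with an estimated correlation). Of 9 adipocyte genes 4 fell (7 adjusted over the list alone), among them Ucp1 (−3.89), with a median of −1.49 (adjusted p = 1.2e-08, and adjusted p = 0.119 with an estimated correlation). Dbh (−1.20, SE 0.25, adjusted p = 0.0151) and Prph (−2.75, SE 0.44) fell, while Mycn (−1.24, adjusted p = 0.382) and Cenpe (0.30, 0.462) did not pass. The Dbh call was lost without small replicate 4 (0.0561) or medium replicate 2 (0.0508).

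Other lists passed with few members past the threshold. MYC targets had a median of 0.27 with 1 of 15 up, Ddx21 at 0.44 (7 adjusted over the list alone; list adjusted p = 1.9e-04; adjusted p = 0.119 with an estimated correlation). Neuronal genes had a median of −0.22 with 1 of 23 down (7 adjusted over the list alone; 0.00148, and adjusted p = 0.119 with an estimated correlation), and Schwann cell genes a median of −1.09 with 1 of 10 down, Cryab (5 adjusted over the list alone; 0.00278, and adjusted p = 0.0953 with an estimated correlation). Noradrenergic genes (median −0.26, adjusted p = 0.0203, and adjusted p = 0.23 with an estimated correlation) and adrenal cortex genes (−0.33, 0.0228, and adjusted p = 0.168 with an estimated correlation) were lower. The adrenal cortex list includes Mrap, named above beside muscle and fat genes, so its call cannot be read as a loss of adrenal tissue. Fibroblast (−0.38, 0.0163), immediate-early (−0.31, 0.0228), cholesterol (−0.26, 0.0495) and kinetochore genes (0.18, 0.022) each had an adjusted p of 0.466 with an estimated correlation, mitotic genes (0.15, 0.0203) an adjusted p of 0.399 and replication genes (0.13, 0.0495) an adjusted p of 0.529 with an estimated correlation. Single arrays decided some of these calls. The cholesterol call was lost without small replicate 2, 4, 5 or 6 or medium replicate 1, 2, 4, 5 or 6 (0.0503 to 0.134). The replication call was lost without small replicate 1, 2, 3 or 6 or medium replicate 3, 5 or 6 (0.0736 to 0.174), with a median of 0.07 without medium replicate 3. Immediate-early genes did not pass without small replicate 1, 2 or 4 or medium replicate 1, 4 or 6 (0.0505 to 0.131), nor kinetochore genes without small replicate 1 or 6 or medium replicate 5 (0.0543 to 0.110). Adrenal cortex genes did not pass without small replicate 2 or medium replicate 1 or 4 (0.0529 to 0.121), fibroblast genes without small replicate 3 (0.0542) or 6 (0.0624) and mitotic genes without small replicate 6 (0.0624). The neuronal median was −0.35 without small replicate 1. limma called 317 probes, 105 higher and 212 lower, or 3 and 111 without normalization. The count fell to 2 with the tissue covariates and to 174 with life span, and it was 137 without small replicate 4 and 174, 169 and 166 without medium replicates 2, 3 and 6.

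Muscle and fat genes were lower in large tumors too. Cox8b (−5.19, SE 0.75), Thrsp (−5.09), Ucp1 (−4.47), Cox7a1 (−3.93) and Pdk4 (−3.79) fell, while Ntsr2 (1.22, SE 0.19), the sirtuin Sirt7 (1.18), Cnot3 (0.92), the histone methyltransferase Setd1a (0.91) and B3galnt2 (0.87) rose. Muscle genes had 9 of 12 down (12 adjusted over the list alone), Acta1 at −5.86, and a median of −4.74 (adjusted p = 2.3e-09; adjusted p = 0.159 with an estimated correlation). Adipocyte genes had 5 of 9 down (9 adjusted over the list alone) and a median of −1.64 (adjusted p = 1.7e-08, and adjusted p = 0.14 with an estimated correlation). Beside them, Dbh fell by 0.94 (adjusted p = 0.0433), Chgb rose by 1.18 and Maoa fell by 0.55, while Mycn (−1.89, adjusted p = 0.0618) and Cenpe (0.43, 0.139) did not pass. Mycn passed without large replicate 3 (0.0307) or 5 (0.0367), and the Dbh call was lost without small replicate 4 or 5 or large replicate 1, 2, 4 or 6 (0.0609 to 0.123).

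Of 15 MYC target genes 3 rose (7 adjusted over the list alone), Srm by 0.67, with a median of 0.34 (adjusted p = 1.5e-04, and adjusted p = 0.151 with an estimated correlation). Replication genes had a median of 0.27 (4.2e-04, and adjusted p = 0.33 with an estimated correlation) and kinetochore genes 0.14 (0.0249, and adjusted p = 0.406 with an estimated correlation), both with none past over all probes in limma. Neuronal genes fell in 4 of 23 and rose in 1 (10 and 1 adjusted over the list alone), with a median of −0.28 (0.00126; adjusted p = 0.151 with an estimated correlation). Schwann cell genes fell in 2 of 10 (5 adjusted over the list alone; median −1.19, 0.0133, and adjusted p = 0.14 with an estimated correlation). Fibroblast genes fell in 4 of 19, Dcn at −3.02 (median −0.34, 0.015, and adjusted p = 0.406 with an estimated correlation), immediate-early genes in 2 of 16, Dusp1 at −0.85 and Nr4a1 at −1.77 (−0.36, 0.0216, and adjusted p = 0.406 with an estimated correlation). Interferon genes fell in 2 of 9 (−0.62, 0.015, and adjusted p = 0.33 with an estimated correlation) and adrenal cortex genes in 1 of 5 (−0.53, 0.0424; adjusted p = 0.246 with an estimated correlation). That 1 gene was Mrap (−3.65), while Fdx1 (−0.53), Cyp21a1 (−0.55) and Scarb1 (0.09) did not pass. The adrenal cortex call was lost without small replicate 1, 2 or 5 or large replicate 1, 2 or 3 (0.0552 to 0.143), with a median of −0.33 without small replicate 2. The kinetochore call was lost without small replicate 1 or 6 or large replicate 1, 2 or 6 (0.0594 to 0.116), with a median of 0.09 without small replicate 6. Immediate-early genes did not pass without small replicate 1 (0.0861) or large replicate 2 (0.0644), and interferon genes without small replicate 1 (−0.26, 0.104). Fibroblast genes did not pass without small replicate 6 (0.0541) or large replicate 3 (−0.23, 0.0753), and had a median of −0.53 without large replicate 4. The replication median was 0.18 without large replicate 6. limma called 761 probes, 313 higher and 448 lower, or 112 and 386 with centred arrays and 4 and 172 without normalization. The count was 4 with the tissue covariates, 273 with life span, 372 without small replicate 4, and 492 and 479 without large replicates 4 and 6.

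No probe separated very large from large tumors in limma (0 past the threshold, 1689 at an unadjusted p under 0.05, lowest adjusted p 0.251). Gdpd2 (2.55, SE 0.50) and Hoxd9 (−2.47), which stood at the extremes, did not pass. In camera, myeloid genes were higher (median 0.29, adjusted p = 0.00499, and adjusted p = 0.72 with an estimated correlation), as were ribosomal proteins (0.05, 0.034; adjusted p = 0.817) and immediate-early genes (0.18, 0.0474; adjusted p = 0.866), and cholesterol synthesis genes were lower (−0.19, 0.00857, and adjusted p = 0.72 with an estimated correlation). No member of these lists passed singly, and without normalization the myeloid median was −0.02 and the immediate-early one −0.11 against −0.21 for all probes. The myeloid call was lost without large replicate 3 (0.14, 0.109) or 6 (0.12, 0.182), and the cholesterol call without large replicate 3 (0.126) or 6 (−0.11, 0.148), with a median of −0.29 without large replicate 4. The ribosomal call was lost without large replicate 2 or 6 or very large replicate 2 or 4 (0.0509 to 0.558), with a median of 0.03 without large replicate 6 and of 0.09 without large replicate 4 or 5 or very large replicate 3. The immediate-early call was lost without large replicate 2, 4 or 6 or very large replicate 1 or 2 (0.0938 to 0.187), with a median of 0.10 without large replicate 6 and of 0.28 without large replicate 5. Without very large replicate 5 the count was 4, and without very large replicate 1 it was 1.

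Across all 24 tumors, levels were related to log10 weight. A slope cannot tell a steady change from a step between the small class and the rest, and no probe separated very large from large tumors. Hbb-y rose by 1.92 log2 units per 10-fold weight (SE 0.36, adjusted p = 0.0016), Alas2, the first enzyme of heme synthesis in red cells, by 1.91 (SE 0.43), Hba-a1 by 1.70, Hbq1a by 1.52 and the interferon-induced exonuclease Isg20 by 1.40. Muscle genes fell, with 10 of 12 past (12 adjusted over the list alone), Tnnt3 at −4.15 (2 of 24 arrays at the floor), Tnni2 at −3.97, Myl1 at −3.91 and Tnnc2 at −3.53, and a median of −3.10 (adjusted p = 1.1e-06, and adjusted p = 0.29 with an estimated correlation). Adipocyte genes fell beside them, 5 of 9 (9 adjusted over the list alone), with a median of −1.19 (2.4e-06, and adjusted p = 0.288 with an estimated correlation). Mycn fell by 1.65 per 10-fold weight (SE 0.36, adjusted p = 0.0057), Dbh (−0.72, 0.0219) and Cdkn1a (−1.20, 0.031) fell too, and Cenpe rose by 0.37 (SE 0.09, 0.0172). With life span as a covariate the slopes were −1.03 for Mycn (adjusted p = 0.268), −0.30 for Dbh (0.565), −1.31 for Cdkn1a (0.156) and 0.36 for Cenpe (0.155), so all 4 calls were lost while the slopes of Cdkn1a and Cenpe stayed near their former values. With the tissue covariates the calls were lost at −1.52 (0.347), −0.63 (0.482), −0.88 (0.632) and 0.27 (0.566). The Cenpe call was also lost with centred arrays (0.22, 0.262) and without small replicate 4 (0.0566) or 6 (0.0522), and that of Dbh without small replicate 4 (0.0982), small replicate 5 (0.0574) or very large replicate 5 (0.0591). The Cdkn1a call was lost without small replicate 2, 3, 4, 5 or 6 (0.0507 to 0.0786), and its slope was −0.79 without very large replicate 4.

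**Figure D2:**
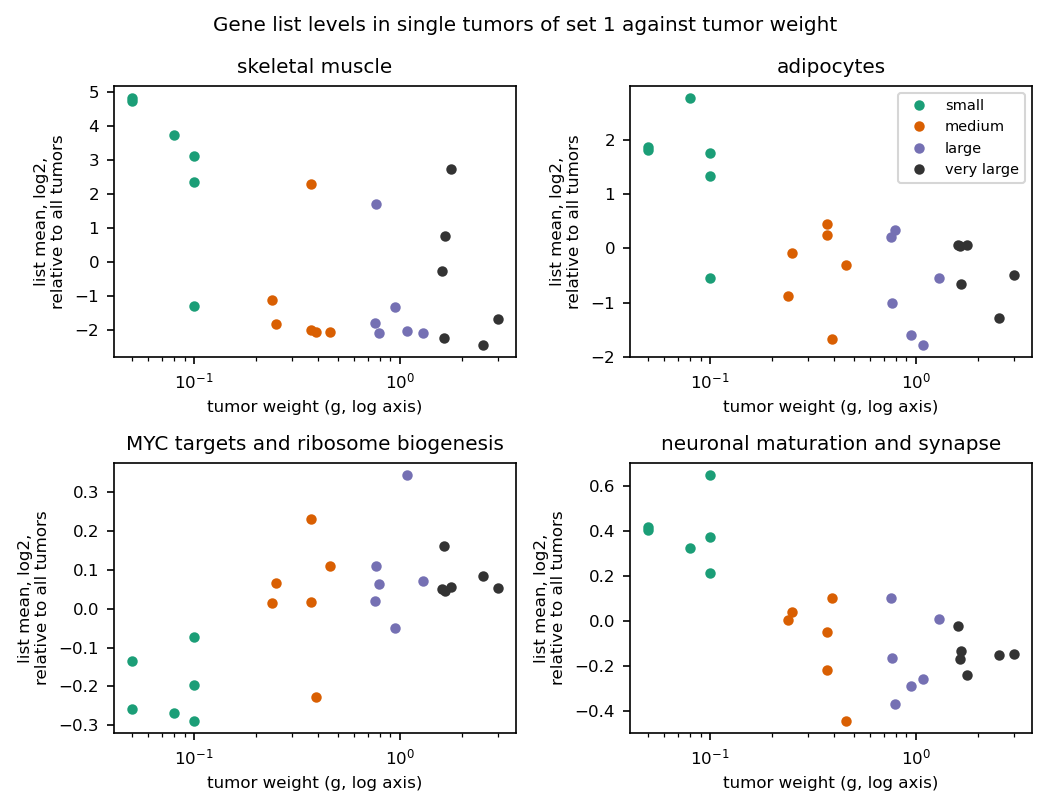
Mean log2 level of 4 gene lists in each of the 24 tumors of set 1 (points, coloured by size class, n = 6 each), relative to the mean of all tumors, against tumor weight in g on a log axis. The muscle list averaged 2.91 in small tumors and −1.12, −1.27 and −0.52 in medium, large and very large ones.

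Of 15 MYC target genes 5 rose with weight (9 adjusted over the list alone), with Srm at 0.47 and Nolc1 at 0.39, and a median of 0.20 (adjusted p = 5.8e-04; adjusted p = 0.288 with an estimated correlation), or 0.05 with centred arrays and −0.14 without normalization against −0.17 for all probes. Kinetochore genes had 2 of 23 up (5 adjusted over the list alone), Cenpe and Spc24 (0.50), and a median of 0.14 (0.0194, and adjusted p = 0.5 with an estimated correlation), which was −0.01 with centred arrays, where the list did not pass. The call was also lost without small replicate 1 (0.0855) or 6 (0.0807). Replication genes had 1 of 19 up (3 adjusted over the list alone), Mcm10 (0.35), and a median of 0.15 (0.00416, and adjusted p = 0.452 with an estimated correlation), which was 0.03 with centred arrays, and the list passed neither without normalization (0.0765) nor with the tissue covariates (0.0659). Neuronal genes fell in 6 of 23 and rose in 2 (9 and 2 adjusted over the list alone), such as Prph (−1.98), Vip (−1.55) and Gal (−0.96), with a median of −0.26 (0.00416, and adjusted p = 0.289 with an estimated correlation; 0.0638 with life span as a covariate). Schwann cell genes fell in 4 of 10 (5 adjusted over the list alone; median −1.02, 0.00265, and adjusted p = 0.0849 with an estimated correlation). Interferon genes fell in 2 of 9 (5 adjusted over the list alone), Cxcl10 at −2.22 and Gbp3 at −0.86 (median −0.54, 0.0109; adjusted p = 0.312 with an estimated correlation), and without small replicate 1 their median was −0.24 and the call was lost (0.0972).

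limma called 1843 probes for the trend, 866 higher and 977 lower with weight, or 247 and 1071 with centred arrays and 19 and 809 without normalization. The count was 0 with the tissue covariates, 247 with life span, 469 on weight without log, 801 without small replicate 4 and 1221 without small replicate 6. For any difference among the 4 sizes limma called 742 probes, 311 without small replicate 4 and 471 without small replicate 6.

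In set 2, day 7 ganglia were compared with day 0 ganglia to follow the lesion through the first postnatal week. No ganglia of mice without the transgene were among the samples. Changes of the lesion and of age therefore cannot be told apart, at day 7 or at day 14. The body level of the ganglia is not given either, and some Hox genes, which record it, differed between the stages, so a difference in level cannot be told apart from them. Cell cycle genes were higher at day 7. Of 19 DNA replication genes 8 rose (14 adjusted over the list alone), with Mcm10 at 2.34, the helicase subunit Mcm5 at 1.91 (SE 0.24) and cyclin E1 (Ccne1) at 1.61, and a median of 1.22 (adjusted p = 1.2e-10, and adjusted p = 0.181 with an estimated correlation). Of 23 kinetochore genes 7 rose (12 adjusted over the list alone), with the centromere histone Cenpa at 2.06, Kif20a at 1.68 and Cenpe at 1.37, and a median of 1.07 (1.8e-08, and adjusted p = 0.312 with an estimated correlation). Of 19 mitotic genes 6 rose (12 adjusted over the list alone), with Cdc25c at 2.04 and Cdc20 at 1.36, and a median of 0.82 (2.6e-06, and adjusted p = 0.312 with an estimated correlation). Adipocyte genes stood higher beside them, 0 of 9 past over all probes in limma and 4 adjusted over the list alone, with a median of 0.95 (0.00248, and adjusted p = 0.181 with an estimated correlation; 0.60 and 0.0696 without day 7 replicate 2), while muscle genes did not pass (−0.14, 0.478).

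Hoxc9, which marks the trunk level of the body axis, rose by 6.99 (SE 0.65, adjusted p = 5.9e-04), from 11.17 ± 0.97 (SD, n = 5) to 18.16 ± 0.17 (n = 2), a lower bound because 1 of 5 day 0 arrays lay at the floor. Retnla (3.66), the lysosomal activator Gm2a (3.62), the glutamate receptor subunit Gria1 (3.42, SE 0.26) and the neuropeptides Vip (3.29) and Npy (2.06) rose, as did Lyz2 of macrophages (1.32) and Mrap (2.13). Plppr1 (−2.59), Lrif1 (−2.54), Bmt2 (−2.52), Olfm3 (−2.37), the Notch target Hey2 (−2.30) and the growth factor Igf2 (−1.08) fell. The changes of Retnla and Mrap (1 of 5 day 0 arrays at the floor) and of Olfm3 (both day 7 arrays) are lower bounds too. Mycn did not pass (−1.16, SE 0.35, adjusted p = 0.111, or −1.41 and 0.00615 without day 0 replicate 1), nor did Th (0.44) or Dbh (0.95). Cenpe rose from 12.39 ± 0.39 (n = 5) to 13.75 ± 0.35 (n = 2), by 1.37 (SE 0.30, adjusted p = 0.0365, range over the alternatives other than single arrays 0.0069 to 0.316). Its call was lost with only these 2 groups in the fit (0.145), on all probes of the series table (0.083), without normalization (0.316), and without day 0 replicate 4 (0.0632) or 5 (0.0551) or day 7 replicate 1 (0.137) or 2 (0.28).

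limma called 252 probes, 187 higher and 65 lower, 118 and 19 on all probes of the series table and 36 and 0 without normalization, which moved the median of all probes by 0.19. The count depended on single arrays: it was 10 without day 7 replicate 2, 50 without day 7 replicate 1, 124 and 160 without day 0 replicates 3 and 4, and 821 and 587 without day 0 replicates 1 and 2, or 3142 without both. Of the 30 called genes named by the rule, 26 lost their call with at least 1 array left out and 0 changed sign.

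Day 14 ganglia were compared with day 0 ganglia for the change over 2 weeks. Of the lists, camera called 10 at the preset correlation, among them glial, immune and neuronal ones higher and imprinted and polycomb ones lower, but 0 with an estimated correlation. Apod, a lipid carrier of glia, rose by 5.19 (SE 0.63, adjusted p = 5.6e-04), followed by the sensory neuron gene Avil (4.67), Ces3 (4.26), the glial receptor Gpr37l1 (4.14), Gpld1 (3.87), the retinoid genes Crabp1 (3.86) and Aldh1a1 (3.71), Cckar (3.83), Tesc (3.45) and endothelin 3 (Edn3, 3.41). Plppr1 (−3.19), Thumpd1 (−2.93), B3gnt5 (−2.89), the cell cycle inhibitor Cdkn1c (−2.86, SE 0.27), Aspn (−2.79), Kcnj11 (−2.78), Tut4 (−2.74), the BMP antagonist Grem1 (−2.71), Fam184b (−2.64) and the nicotinic receptor subunit Chrna4 (−2.62) fell. In each of these 20 genes both day 14 arrays lay outside the range of the 5 day 0 arrays, because the rule for naming genes required it. The changes of Apod, Ces3 and Aldh1a1 (2 of 5 day 0 arrays at the floor) and of B3gnt5, Fam184b and Chrna4 (1 of 2 day 14 arrays) are lower bounds.

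Mycn fell by 1.71 (SE 0.35, adjusted p = 0.0101), from 17.38 ± 0.63 (n = 5) to 15.68 ± 0.13 (n = 2), while Dbh rose by 1.98 (SE 0.33, 0.00324) and Th rose by 0.66 (0.0225). Cenpe did not pass (0.20, SE 0.30, 0.723). The Mycn call was lost without normalization (−0.91, adjusted p = 0.277), where the median of all probes lay at 0.72, so much of that shift was common to all probes. It was also lost without day 14 replicate 1 or 2, as was that of Th, and that of Dbh was lost without day 14 replicate 2. Noradrenergic genes as a list went both ways, 3 of 20 up and 6 down (4 and 7 adjusted over the list alone), with Pnmt at −1.17 and Chga at −0.69. Their median was 0.12, their mean −0.05 and the test negative (adjusted p = 0.271).

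Of 10 MHC class I genes 4 rose, with the immunoproteasome subunits Psmb9 at 2.70 and Psmb10 at 2.34 and H2-D1 at 1.87 (4 adjusted over the list alone; median 0.82, adjusted p = 0.00395; adjusted p = 0.132 with an estimated correlation). Of 9 interferon genes 5 rose, with Oasl2 at 2.53, Gbp3 at 2.21 and Cxcl10 at 1.99 (5 adjusted over the list alone; median 1.37, 0.00395, and adjusted p = 0.297 with an estimated correlation). Of 23 neuronal genes 5 rose (8 up and 2 down adjusted over the list alone), with Npy at 1.57, Chrna3 at 1.21 and Rab3a at 1.10 (median 0.56, 0.0255, and adjusted p = 0.23 with an estimated correlation; 0.0873 without day 0 replicate 5). Of 10 Schwann cell genes 4 rose, with Gpr37l1 as above and Fabp7 at 1.12 (4 adjusted over the list alone; median 0.84, 0.0172, and adjusted p = 0.23 with an estimated correlation; 0.0604 without day 0 replicate 2). Of 14 endothelial genes 2 rose, Cldn5 by 1.87 and Egfl7 by 0.94 (2 adjusted over the list alone; median 0.57, 0.0434, and adjusted p = 0.664 with an estimated correlation). The endothelial call was lost without day 0 replicate 2, 3, 4 or 5 (0.0555 to 0.0988) and without day 14 replicate 2 (median 0.27, 0.323). Adipocyte genes rose beside them in 2 of 9, Cfd by 2.50 and Pnpla2 by 1.12 (4 adjusted over the list alone; median 1.19, 0.0109; adjusted p = 0.132 with an estimated correlation), while muscle genes were lower with 0 of 12 past in limma (median −0.49, 0.0434, and adjusted p = 0.583 with an estimated correlation). The muscle call was lost without day 0 replicate 1, 2 or 5 or either day 14 array (0.0600 to 0.166).

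Of 13 imprinted growth genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Cdkn1c as above, Igf2 at −1.61 (SE 0.16), Grb10 at −1.15 and Impact at 1.99 (median −0.55, adjusted p = 0.00788, and adjusted p = 0.288 with an estimated correlation). Of 13 polycomb and progenitor genes 3 fell (8 adjusted over the list alone), among them Sox11 (−1.47) and Sox4 (−0.92) (median −0.58, 0.00185, and adjusted p = 0.132 with an estimated correlation). Of 30 ribosomal proteins 2 fell (0 adjusted over the list alone), Rpl22 at −0.70 and Rpl4 at −0.68 (median −0.18, 0.0092, and adjusted p = 0.23 with an estimated correlation). Without normalization the medians of these 3 lists turned to 0.24, 0.05 and 0.20, where that of all probes moved by 0.72. The cell cycle lists did not pass: medians were 0.09 for kinetochore (0.58), −0.15 for mitotic (0.271) and 0.29 for replication genes (0.227), although E2f1 (1.76), Ccne1 (1.27) and Zwint (1.27) rose. Fibroblast genes split 3 up, with Mmp2 at 1.52, and 3 down (0.234). The p53 list did not pass either (0.899), with Gadd45a at 1.02.

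limma called 1293 probes, 706 higher and 587 lower, of which 448 and 340 changed at least 2-fold, or 1023 higher and 20 lower without normalization. The count was 143 without day 14 replicate 2, 404 without day 14 replicate 1, 716 without day 0 replicate 3, 2020 without day 0 replicate 1 and 3504 without day 0 replicates 1 and 2 together. Of 70 called genes named by the rule 52 lost their call with at least 1 array left out and 0 changed sign.

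**Figure D3:**
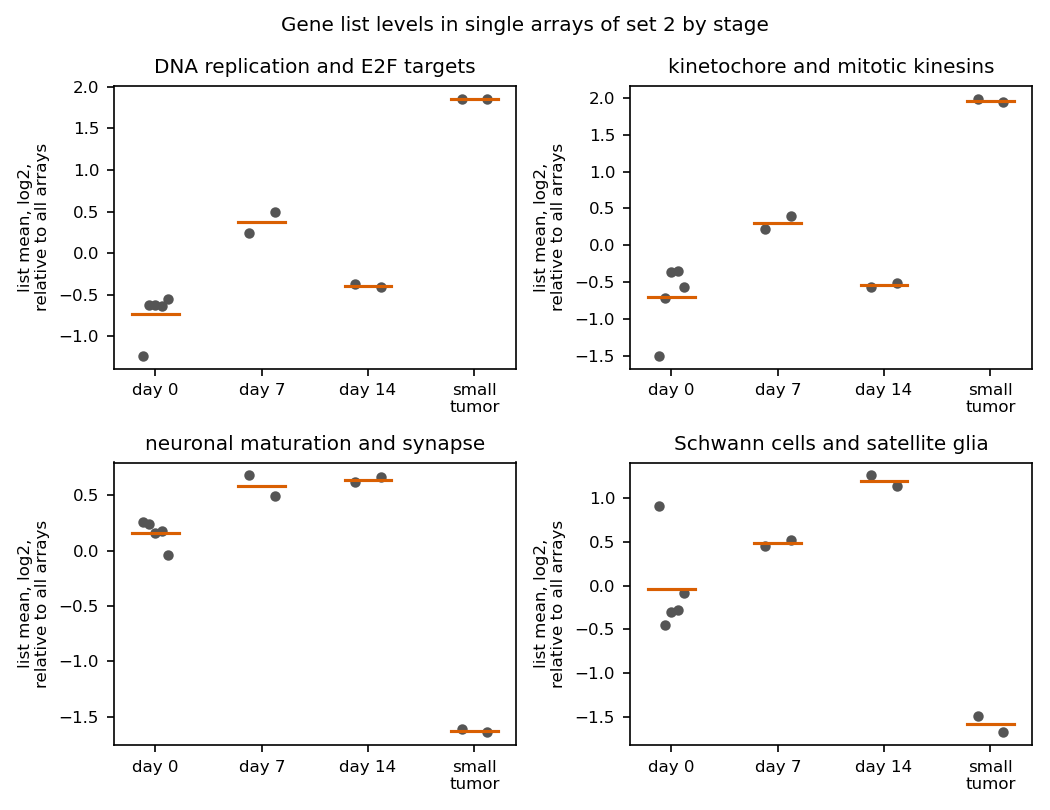
Mean log2 level of 4 gene lists on each of the 11 arrays of set 2 (points) with the group mean (orange bar), relative to the mean of all arrays, for ganglia of day 0 (n = 5), day 7 (n = 2), day 14 (n = 2) and small tumors (n = 2). The list median of the DNA replication genes was 1.22 higher at day 7 and 2.92 higher in tumors than at day 0.

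Between day 7 and day 14 the cell cycle lists fell. Of 19 mitotic genes 2 fell, Tpx2 at −1.46 and Cdc20 at −1.40 (12 adjusted over the list alone; median −0.97, adjusted p = 2.2e-09; adjusted p = 0.133 with an estimated correlation). Of 19 replication genes 2 fell, Mcm5 at −1.52 and Mcm4 at −0.95 (12 adjusted over the list alone; median −0.90, 8.8e-08, and adjusted p = 0.133 with an estimated correlation). Of 23 kinetochore genes 3 fell, Kif23 at −2.02, Kif20a at −1.66 and Cenph at −1.17 (6 down and 1 up adjusted over the list alone; median −1.01, 4.4e-07, and adjusted p = 0.22 with an estimated correlation), and Cenpe did not pass (−1.17, 0.166). Hoxc9 fell by 7.16, a lower bound because 1 of 2 day 14 arrays lay at the floor. So did the opioid precursor Pdyn (−3.40), Gm2a (−3.02), Chrna4 (−2.68) and Cdkn1c (−1.86), and Scgn (2.60), Pctp (2.46), H2-D1 (2.04), Tuba4a (1.88), Fxyd2 (1.83) and Gadd45a (1.49) rose. The changes of Chrna4 and Pctp also had 1 array at the floor.

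MHC class I genes (median 0.76, adjusted p = 1.0e-04, and adjusted p = 0.0962 with an estimated correlation), interferon genes (1.10, 4.2e-05; adjusted p = 0.155) and hypoxia genes (0.42, 0.03, and adjusted p = 0.133 with an estimated correlation) were higher at day 14. Ribosomal proteins (−0.20, 4.2e-05; adjusted p = 0.133 with an estimated correlation), polycomb genes (−0.63, 0.0036; adjusted p = 0.133), imprinted genes (−0.39, 0.0085; adjusted p = 0.267) and fibroblast genes (−0.11, 0.0369, and adjusted p = 0.415 with an estimated correlation) were lower. The fibroblast call was lost without day 7 replicate 2 (−0.28, 0.0697) or day 14 replicate 1 (−0.30, 0.148), and its median was −0.31 without day 7 replicate 1 and −0.22 without day 14 replicate 2. The hypoxia call was lost without day 7 replicate 2 (0.0697) or day 14 replicate 1 (0.0776). Without normalization, which moved the median of all probes by 0.56, the ribosomal and imprinted medians were 0.14 and 0.18. limma called 59 probes, 25 higher and 34 lower. With groups of 2 the call rested on each array: leaving out 1 array left 2 to 7 probes (7 and 3 without day 7 replicates 1 and 2, and 2 without either day 14 replicate).

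Small tumors were compared with day 0 ganglia to ask what separates a tumor from the early lesion. The tumors came from mice of 28 and 42 days, so tumor and age differ together, here and in the comparison with day 14. Muscle and fat signal differed too: the muscle list stood at 2.60 in tumors and −0.44 at day 0, and the adipocyte list at 2.38 and −1.09. No fit with these levels as covariates was run in set 2, so tissue content cannot be separated from tumor in the values below. The 2 tumor arrays had r = 0.989 with each other, and 0.865 and 0.863 with their own set 1 arrays, across separate scalings. Pairs of separate ganglion specimens within set 2 reached 0.985 and 0.984. The differences between the 2 tumor specimens had r = 0.042 between the sets. It is thus not settled whether n = 2 stands for 2 tumors or for 1, here and in the comparison with day 14. If for 1, the SDs, SEs and p values do not cover differences between tumors. The cell cycle lists were higher. Of 19 replication genes 18 rose, Mcm3 by 3.44 and Mcm4 by 2.28 (18 adjusted over the list alone; median 2.92, adjusted p = 8.9e-12, and adjusted p = 0.0717 with an estimated correlation). Of 23 kinetochore genes 21 rose and 1 fell, Cenph by 3.13 (22 and 1 adjusted over the list alone; median 2.94, 1.9e-10, and adjusted p = 0.141 with an estimated correlation). Of 19 mitotic genes 18 rose and 1 fell, the kinase Plk1 by 4.01 (SE 0.26) and Cdc20 by 2.93 (18 and 1 adjusted over the list alone; median 2.91, 9.4e-10, and adjusted p = 0.0964 with an estimated correlation). Cenpe rose from 12.39 ± 0.39 (SD, n = 5) to 15.23 ± 0.16 (n = 2), by 2.84 (SE 0.30, adjusted p = 1.2e-05). MYC targets rose in 11 of 15, Nolc1 by 2.35 (11 adjusted over the list alone; median 1.25, 4.9e-05; adjusted p = 0.0717 with an estimated correlation). Polycomb genes rose in 7 of 13 and fell in 1, Ezh2 by 2.49 (7 and 2 adjusted over the list alone; median 0.92, 0.0369, and adjusted p = 0.204 with an estimated correlation).

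Neuronal and noradrenergic genes were lower. The named genes that fell most were chosen by size of change and not by list, with Prph from the neuronal and Igf2 from the imprinted list. Prph fell by 6.45 (SE 0.26, adjusted p = 8.2e-09), as did gamma-synuclein (Sncg, −5.93), Igf2 (−5.73, SE 0.16), Bdh2 (−5.54), Tm4sf4 (−5.44), Chst8 (−5.36), A030009A06 (−5.22), Snhg11 (−5.19), Lingo2 (−4.95) and Resp18 (−4.92). For Chst8 both tumor arrays lay at the floor, so its change is a lower bound. Mycn fell by 4.01 (SE 0.35, adjusted p = 2.6e-06), from 17.38 ± 0.63 (n = 5) to 13.37 ± 0.06 (n = 2). Of 23 neuronal genes 17 fell, Gal at −4.52 and Syn2 at −3.87 (19 adjusted over the list alone; median −1.55, 1.3e-07, and adjusted p = 0.0282 with an estimated correlation). Of 20 noradrenergic genes 13 fell and 1 rose, with Dbh at −3.66, Th at −2.34 and Gch1 at −2.34 (13 and 1 adjusted over the list alone; median −0.96, 1.6e-05, and adjusted p = 0.222 with an estimated correlation). Schwann cell genes fell in 5 of 10, Fabp7 at −2.78 (6 adjusted over the list alone; median −1.74, or −1.12 without day 0 replicate 1, 0.0046, and adjusted p = 0.144 with an estimated correlation), fibroblast genes fell in 12 of 19 and rose in 1, with Mmp2 at −3.41 (13 and 1 adjusted over the list alone; median −0.84, 2.4e-04; adjusted p = 0.163 with an estimated correlation), and cholesterol genes fell in 10 of 17 (11 adjusted over the list alone; median −0.72, 0.00132, and adjusted p = 0.204 with an estimated correlation).

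Muscle, fat and macrophage genes were higher in the tumors than in day 0 ganglia, beside all the lists above. Muscle genes rose in 9 of 12 and fell in 3, Tnnt3 by 6.75, Tnnc2 by 6.37 and Tnni2 by 5.72 (9 and 3 adjusted over the list alone; median 3.96, adjusted p = 1.3e-04, and adjusted p = 0.204 with an estimated correlation). Adipocyte genes rose in 8 of 9, Cfd by 6.82 and Pck1 by 5.70 (8 adjusted over the list alone; median 3.08, 3.0e-05, and adjusted p = 0.0282 with an estimated correlation), as did Ces3 (7.10), Cox8b (5.76) and Thrsp (5.70). Myeloid genes rose in 11 of 15, Lyz2 by 3.94 (SE 0.21) and Ctss by 1.76 (11 adjusted over the list alone; median 1.63, 3.0e-05, and adjusted p = 0.144 with an estimated correlation). Hoxc9 rose by at least 6.45 and Hoxa5 by at least 5.71, since 1 and 2 of 5 day 0 arrays lay at the floor, and the rises of Ces3 (2 of 5) and Pck1 (1 of 5) are lower bounds too. Ribosomal proteins rose in 16 of 30 and fell in 5 (17 and 5 adjusted over the list alone; median 0.52, 0.00788; adjusted p = 0.163 with an estimated correlation), and without normalization their median of 0.84 lay below the 0.92 of all probes and the test turned negative. Several ribosomal protein genes, among them Rpl7 and Rps2, had a second probe called the other way.

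The other 9 lists did not pass, with adjusted p values from 0.214 for the adrenal cortex and 0.233 for imprinted genes to 0.988 for p53 targets. Among imprinted genes 4 rose, Slc38a4 by 3.81 and Dlk1 by 3.05, and 5 fell, Igf2 as above and Impact at −4.58. Of 18 hypoxia genes 2 rose, the hexokinase Hk2 by 3.72, and 6 fell. limma called 4734 probes, 2336 higher and 2398 lower, of which 1548 and 1660 changed at least 2-fold, or 3876 and 428 without normalization. The count was 2882 and 2902 without set 2 tumor replicates 1 and 2. Of 100 called genes named by the rule 11 lost their call with at least 1 array left out and 0 changed sign.

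The same 2 tumor arrays were compared with day 14 ganglia, so the comparisons are not independent. Tnnt3 (7.85), Tnni2 (7.01), Tnnc2 (6.81), Hoxc9 (6.62) and Actc1 (5.87) rose, those of Tnnt3 and Hoxc9 as lower bounds because 1 of 2 day 14 arrays lay at the floor, and Sncg (−7.58), Prph (−7.23), Tspan8 (−6.71), Fbxo2 (−6.68) and Impact (−6.56) fell. Cenpe rose by 2.65 (SE 0.35, adjusted p = 9.6e-05), Mycn (−2.30, SE 0.41, 8.2e-04), Dbh (−5.63) and Th (−3.01) fell, while Sox11 (3.43) rose and Oasl2 (−4.76) and Psmb10 (−3.15) fell. Neuronal genes fell in 18 of 23 (median −1.93, adjusted p = 4.3e-08, and adjusted p = 0.0363 with an estimated correlation). Kinetochore (median 2.74, 1.7e-08, and adjusted p = 0.133 with an estimated correlation), mitotic (3.12, 6.9e-09; adjusted p = 0.0917) and replication genes (2.72, 6.9e-09, and adjusted p = 0.0917 with an estimated correlation) were higher. So were MYC targets (1.18, 7.3e-05, and adjusted p = 0.083 with an estimated correlation), polycomb genes (1.82, 0.00134; adjusted p = 0.0917) and ribosomal proteins (0.67, 0.00134; adjusted p = 0.101 with an estimated correlation).

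Muscle genes rose in 9 of 12 and fell in 3 (median 4.70, adjusted p = 1.0e-04, and adjusted p = 0.221 with an estimated correlation), adipocyte genes rose in 7 of 9 (2.13, 0.00157, and adjusted p = 0.083 with an estimated correlation) and myeloid genes in 9 of 15 (1.48, 7.3e-05, and adjusted p = 0.133 with an estimated correlation). Schwann cell genes fell in 7 of 10 (−2.93, 3.7e-04, and adjusted p = 0.0917 with an estimated correlation), noradrenergic genes in 9 of 20 with 2 up (−1.11, 0.00576; adjusted p = 0.461), fibroblast genes in 8 of 19 with 1 up (−0.92, 0.0128; adjusted p = 0.308) and cholesterol genes in 11 of 17 (−0.89, 0.00174; adjusted p = 0.223 with an estimated correlation). limma called 5043 probes, 2522 higher and 2521 lower, 1957 without normalization and 3315 without set 2 tumor replicate 1. For any difference among the 4 stages it called 5319 probes, 3213 and 3234 without tumor replicates 1 and 2.

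The fold changes of the sets were set side by side, very large against small tumors in set 1 and small tumors against day 0 ganglia in set 2. Across 12688 probes r was 0.222 (jackknife SE over arrays 0.0462) and rho 0.310, or 0.234 and 0.304 without the 2 shared specimens. Probes are not independent, and no p is given. Mycn and Dbh fell and Cenpe rose in both comparisons, whereas the muscle and adipocyte lists fell in set 1 (medians −3.87 and −1.62) and rose in set 2 (3.96 and 3.08).

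The 2 small tumors hybridised in both sets were compared array by array, across the separate scalings. Small replicate 3 had r = 0.865 with its own array of set 2, against 0.838 to 0.869 for the other small tumors, and ranked 3 of 6. Small replicate 6 had r = 0.863 with its own, against 0.832 to 0.858, and ranked 1 of 6. In set 2 the 2 tumors had r = 0.989 with each other. Tnnt3 of fast muscle stood at 7.91 in small replicate 3 in set 1 and 17.42 in set 2, and at 17.41 and 17.85 for small replicate 6.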

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

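The tests of muscle content in set 1 and of the repeated tumors in set 2 were chosen after the results they measure had been seen, whereas those of the day 7 cell cycle lists were chosen before. In 20 of 155 groups of 5 or 6 arrays (12.9%) the highest or lowest array lay far from the nearest other one relative to the group's range. Chance does so in about 1 in 20 groups. List levels below are means of log2 values relative to all arrays of the set, and gene levels are log2 intensities.

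Muscle and adipocyte lists stood higher in small tumors than in larger ones, with the muscle list at 2.91 ± 2.27 (SD, n = 6) and Tnnt3 between 7.91 and 18.43 among the 6 small tumors. Normalization between arrays is argued against as the cause, since the median of the muscle list was −4.16 without it and −3.87 with it. Neighbouring muscle in the sections may account for the pattern and stays open, while fat was not tested by itself, as the muscle level says little of it (r = 0.151 between the lists within size classes): over the 796 probes called lower outside these lists, the median r with the muscle list within size classes was 0.097 (jackknife SE 0.0472), against −0.012 for the 31435 probes not called and −0.089 for the 742 called higher. A value under 0.1 had been set to exclude it, and it was left open, after the value was seen, because 0.097 lies within its spread of that bound. A gradual loss with weight, the biological reading, was not seen above the small class, with rho at −0.0764 (permutation p = 0.763, 2-sided) over those 18 tumors. The muscle list averaged −1.12 ± 1.71 in medium, −1.27 ± 1.48 in large and −0.52 ± 2.01 in very large tumors (SD, n = 6 each). The drop thus lay between small and medium tumors. As the spread is wide, a gradual loss is not excluded, and the 2 readings cannot be told apart here.

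The set 2 arrays of the 2 small tumors had r = 0.989 with each other, and 0.865 and 0.863 with their own set 1 arrays, across separate scalings. Pairs of separate ganglion specimens within set 2 reached 0.985 and 0.984. The differences between the 2 tumor specimens had r = 0.042 between the sets, across 12688 probes. The muscle list differed by −5.04 between the specimens in set 1 and by −0.09 in set 2. If both set 2 arrays held a single specimen, or if another section with more muscle was used, probes that differed between the specimens in set 1 could tell, since chance gives the same sign in set 2 in 50% and the latter in more. Of bright probes away from muscle and fat with a 4-fold difference 2 remained, 50% of the same sign, and at 2-fold, tried because so few were left, 19 remained, 47.4% of the same sign (SE 11.5). Fewer than 50 probes allow no verdict, so both explanations stay open and cannot be told apart, and no biological explanation was tested.

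Cell cycle lists stood higher in day 7 than in day 0 ganglia, with a median of 1.22 for the DNA replication list. Differences among the day 0 specimens are argued against: the median was 1.06 against the less favourable of the 2 specimen series of day 0 (camera adjusted p = 3.2e-06). So is normalization (1.48, 1.6e-11, without it), and so is a single day 7 array (0.905, 1.8e-07, with the less favourable one left out). The hypothesis that cells at day 7 divide more remains, but a share of the genes' common variation could give the same call, as the list had an adjusted p of 0.181 with an estimated correlation. Age and specimen differ together between these groups, with 2 arrays at day 7. Hoxc9 differed between them too, and a difference in the body level of the ganglia was not tested.

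The muscle list stood at 2.29 in medium replicate 5 and at 1.70 in large replicate 1. DNA replication genes stood at 0.50, heat shock genes at 0.46 and ribosomal proteins at −0.28 in large replicate 6. In very large replicate 4 the p53 list stood at −0.78, interferon genes at 0.27 and Cdkn1a at 7.73 (nearest other 11.66). In medium replicate 3 the p53 list stood at −0.32 and Cdkn1a at 11.42 (nearest other 12.28). Noradrenergic genes stood at 0.33 in large replicate 4, MYC targets at 0.16 in very large replicate 3, polycomb genes at −0.13 in medium replicate 2 and heat shock genes at 0.41 in small replicate 4. Dbh stood at 12.04 in very large replicate 5 (nearest other 12.72). Day 0 replicate 1 differed from the other 4 day 0 arrays in DNA replication (−1.23), polycomb (−0.38), noradrenergic (−0.42) and Schwann cell genes (0.91) and in Th (20.82, nearest other 21.27).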

How the results depend on the processing

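Of the alternatives, those without normalization, with muscle and adipocyte levels as covariates, without 3 arrays that stood apart and without day 0 specimens were chosen after seeing the data. So were those on the authors' probes of the series table and, for the fold changes of the sets, with either shared specimen left out alone. The others were chosen before. Among named genes 9229 comparisons with an alternative gave the same result, 1436 lost the call, 27 gained it and 21 turned. Among gene lists the numbers were 3906, 276, 103 and 9. The same result includes genes and lists called in neither fit, and settings that move nothing. These totals therefore do not measure how many calls held. List directions here are those of the camera test, so that a median may turn without being counted, as for the set 1 cell cycle lists, whose kinetochore median was 0.01 with centred arrays. For set 2 a further quantile normalization or centring moves nothing, because all arrays already share the same values. No paired analysis was possible because replicate numbers only name the samples. Signal over background is not given in the sources used here. Where no reason is given, the cause was not tested.

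Counts of probes that moved by more than 1.5 times are given by setting. Without the intensity trend limma called 403 for any size difference, 173 for medium, 393 for large and 964 for very large against small, 165 for day 7 against day 0 and 24 for day 14 against day 7. With array weights it called 1322 for any size, 805 for medium against small, 9465 for any stage, 3520 for day 7, 5577 for day 14 and 7409 for tumors against day 0, and 1106 for day 14 against day 7. With life span as a covariate it called 152 for any size, 174, 273 and 272 for medium, large and very large against small, and 247 for the trend. With centred arrays large against small gave 498. With only the 2 groups in the fit large against small gave 462, day 7 and day 14 against day 0 gave 31 and 647, and day 14 against day 7 gave 862. Weight without log gave 469 for the trend. On all probes of the series table day 7 gave 137, day 14 gave 807 and day 14 against day 7 gave 34.

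Among settings chosen after seeing the data, no normalization gave 271 for any size, 114, 176 and 552 for medium, large and very large against small and 828 for the trend, and in set 2 it gave 36 for day 7, 2 for day 14 against day 7 and 1957 for tumors against day 14. With muscle and adipocyte levels as covariates the counts were 2, 2, 4, 12 and 0 for any size, medium, large, very large and the trend; these covariates differ between the classes and take up part of the class difference. Without the 3 arrays that stood apart medium against small gave 556. Without day 0 replicates 1 and 2 day 7 gave 3142 and day 14 gave 3504.

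Of the lists called, 10 for very large against small, 8 for the trend, 10 for day 14 and 14 for tumors against day 0, an estimated correlation left 0, 0, 0 and 2. The tissue covariates left 4 for very large against small and 4 for the trend, and without the dimmer probes (50%) 4 were left at day 14, where 17 of the 23 lists could still be tested, 1 call was lost and 5 called lists had too few genes left. Spearman's rho of the repeated tumors with their own arrays was 0.849 and 0.848.

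Some values turned. The muscle list and its members Casq1, Myl1, Tnnc2 and Tnnt3 were among them with the tissue covariates, which hold that list's own level and so bring it near 0 by construction. With these covariates the lists gave for medium against small fibroblasts −0.0655, muscle −0.0359 and immediate-early genes 0.0109 (in these the test turned, not the median of the first 2), for large against small muscle 0.0461 and immediate-early genes 0.0229, and muscle 0.202 for very large and 0.0395 for the trend. Among genes Cryab gave 0.0309, Casq1 0.268 and Myl1 0.0591 in large, Casq1 0.197 and Tnnc2 0.0343 in very large tumors, and Tnnt3 0.0545, Myl1 0.78, Tnnc2 0.0245 and Casq1 0.396 in the trend. Without normalization Ipo4 gave −0.071 and Syt1 −0.0125 in very large tumors, Ddx21 −0.0100 and Ipo4 −0.0585 in the trend, Rpl4 0.10 and Bbc3 0.15 at day 14, and P4ha2 0.11, Irf9 0.23, Psmb10 0.11, Phlda3 0.13 and the ribosomal list 0.84 in tumors against day 0. Without the 3 arrays that stood apart the test of ribosomal proteins turned in very large against large tumors (median 0.0153). With probes averaged per gene Rpl7 gave 0.15 and Dnaja1 −0.10 in tumors against day 14.

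With each array left out in turn, counts ran from 311 to 868 for any size, 137 to 403 for medium, 372 to 806 for large and 827 to 2017 for very large against small, 0 to 4 for very large against large and 801 to 2142 for the trend. In set 2 they ran from 3213 to 6042 for any stage, 10 to 821 for day 7, 143 to 2020 for day 14, 2 to 7 for day 14 against day 7, 2882 to 4942 for tumors against day 0 and 3315 to 3506 against day 14. The low ends were reached without small replicate 4 in every set 1 comparison with small tumors, without a tumor array, without day 7 replicate 2 and without day 14 replicate 2. Where this left a group with 1 array, its spread was assumed to be that of the other groups. Lists called ran from 7 to 12 for very large against small, 7 to 11 for the trend, 7 to 9 for day 14 and 14 to 14 for tumors against day 0.

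Of 100 splits of the same tumors, the real one included, 1 gave as many probes as the 742 for any size (highest other 2), 2 as many as the 317 for medium (highest other 484), 1 as many as the 761 for large (highest other 237), 1 as many as the 1549 for very large against small (highest other 35) and 1 as many as the 1843 for the trend (highest other 1). At a level of 0.05, not adjusted over the comparisons, chance was unlikely to give these counts. The case of medium against small is the weakest, as another split gave 484 probes, more than the real 317. For very large against large 100 of 100 splits gave at least the 0 probes found (highest other 1), which holds by construction. The splits therefore cannot bear on chance there.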

Other observations

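The Hox values here were chosen after they had been seen, and no explanation of them was tested. Some Hox genes, which record position along the body axis, differed between the ganglia of set 2, and not in the same way. Hoxc9 stood at a log2 level of 18.04 and 18.28 in the day 7 ganglia and at 17.63 and 17.61 in the tumors, but between 9.78 and 12.31 in the day 0 ganglia and at 12.21 and 9.78 in those of day 14, where 9.78 is the floor. Hoxd9 stood at 13.91 and 14.22 at day 7 and at 14.25 and 14.21 at day 14, against 11.31 to 12.27 at day 0, and Hoxc4 lay between 11.87 and 12.67 in all 9 ganglia. In set 1 Hoxc9 lay between 14.60 and 16.08 in all 24 tumors, on a separate scale. Day 0 replicate 1 was the highest of the day 0 ganglia for Hoxb2 (16.47 against 13.63 to 14.34), Hoxb4 (18.09 against 11.99 to 13.72), Hoxb5 (16.79 against 11.44 to 12.37) and Hoxb6 (17.48 against 9.78 to 12.09). In set 1, small replicate 5 had Hoxb2 at 17.51, against 8.15 to 11.37 in the other tumors. The labels do not say from which level of the body the ganglia were taken.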
